A study of Homo sapiens with 2 samples.

How the data were processed

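RNA was measured in 2 libraries of primary human lung microvascular endothelial cells, obtained commercially and cultured between passage 4 and 7. The cells were electroporated with a control siRNA or an siRNA against SOX17 and collected at 48 h, and equal amounts of RNA from 3 replicates per condition were pooled, per the series' design text and the labels' protocols. The groups are control siRNA and SOX17 siRNA, with 1 library each. Pooling averages the replicates, so their spread cannot be recovered. Total RNA was isolated with a column kit and DNase treatment, per the labels' protocols. How ribosomal RNA was removed and whether the libraries keep strand are not given in the sources used here.

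Reads were aligned with HISAT2 to GRCh38 and compared with Cuffdiff, per the submitters' processing notes, which give no versions. The FPKM values per gene and library are those the authors deposited, in the layout of a Cuffdiff gene table, per the file headers. How Cuffdiff scaled the libraries is not given in the sources used here. The p-value and the q-value of each row are also deposited by the authors, per the file headers, and come from a comparison of 2 single libraries. The column that marks which rows were tested was not used here, since the table as held carries none. The log2 fold change column was checked against the FPKM values: 99.99% of the finite entries were within 0.01 of the log2 ratio of the 2 values. Identifiers that begin with MSTRG show gene models merged from assembled transcripts. Of 57320 rows, 2107 carried several symbols because overlapping genes share a model, and their reads cannot be told apart. Such rows were kept and counted in a list a single time. Rows named only "-" (196) and rows named only by a clone identifier (690 past the filter) were left out of the named comparisons, as were Y-linked genes and XIST. Clone identifiers were read as identifiers without a symbol, a choice made after the files were seen. Locus starts in the table count from 0: for 22261 genes with 1 annotated transcript, 62.3% of starts equalled the GENCODE release 29 start after adding 1, and 0.0854% as written. Coordinates are printed with 1 added, and a locus can be wider than the gene, since overlapping models share it.

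Read counts were not used here. What 1 fragment is worth was estimated from genes with 1 annotated transcript of at least 1500 bases. Values between 0.03 and 0.08 FPKM times kb were kept. Their median was 0.0595 in the control library (78 genes) and 0.0571 in the SOX17 siRNA library (95 genes). The window bounds these medians, so they do not show by themselves that the values fall on a step. The inverses of the medians, scaled to whole libraries as 16800000 and 17500000 fragments, are approximate and depend on the window. Of 285 low genes present in both libraries, the 87 with a log2 ratio below 0.2 in size had a median relative worth of 0.973, which that limit also bounds. Precision from counting error followed from these numbers as a 95% half-width of the log2 ratio with its pseudocount, and covers counting error only.

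A gene entered the comparison with at least 1 FPKM in at least 1 library, which left 11210 genes. Log2 ratios used a pseudocount of 1. With 1 library per group no test was run and no p-value was computed across genes. Genes at least 2-fold higher or lower on this scale were counted. The spread beside a single gene is the robust spread (1.4826 times the median absolute deviation) of log2 ratios of the 500 genes nearest in mean level. For 37 gene lists fixed before the data were examined, the median log2 ratio of the measured members was set against the medians of 10000 random lists of the same size drawn from the members' own bins of mean level (20 bins, seed 7). Lists with fewer than 5 measured rows are given as values. Named genes followed a rule that was also fixed before the data were examined: SOX17, SOX7, SOX18 and E2F1, the 12 highest and 12 lowest log2 ratios among genes with a symbol and at least 5 FPKM, and from each list up to 3 members with the highest and 3 with the lowest log2 ratio, or any member of a list of 20 or fewer genes. Any other gene is said to have been chosen after its values were seen.

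The size rule and the list percentile were tested on simulated data. Both libraries of a pair were drawn with Poisson counts around each gene's mean over the 2 real libraries. A single depth was used, from the average of the 2 estimates of what 1 fragment is worth. In the second library 200 genes were changed by 3-fold or 1.5-fold. Of 11090 simulated genes past the filter, the rule recovered 99% of those changed 3-fold and 0% of those changed 1.5-fold, and it called 10 unchanged genes. The changed genes had at least 5 FPKM, so with a rule of 2-fold both recovery rates followed largely from the threshold. A planted list of 30 genes at 1.3-fold lay at percentile 100, and 4.5% of 200 lists without a change lay outside the central 95%. The lists without a change came from the same independently drawn genes as their random lists, so a share of this size was given by construction. The simulation held no genes that vary together and no differences between cultures. It therefore cannot show how often real lists lie outside without a change.

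Trends of the log2 ratio with transcript length, GC content and level were fitted by robust regression on B-splines with 4 degrees of freedom each, on genes with a single symbol outside the list in question, with length and GC of the longest protein-coding transcript in GENCODE release 29. All list members had these values, above the minimum of 80%. Alternatives changed 1 choice at a time: pseudocounts of 0.1 and 0.5, other filters, 3 rescalings of the libraries, thresholds of 1.5-fold and 3-fold, unmatched random lists or 10 bins, means in place of medians, and the list without its member of largest difference. Alternatives added after seeing the data were rows with a single symbol, rows whose p-value in the authors' deposited table is below 1, clone-named rows kept, and residuals after the trends. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6, patsy 1.0.2 and matplotlib 3.10.9.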

Results

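The data consisted of 2 RNA-seq libraries from primary human lung microvascular endothelial cells, the cells that line the small vessels of the lung. Cells between passage 4 and 7 were electroporated with a small interfering RNA (siRNA) against SOX17, a transcription factor of the SOXF group, or with a control siRNA, and were collected after 48 h. Equal amounts of RNA from 3 replicates were pooled in each condition before library construction, so each group had 1 library, no value has a replicate error, and no comparison has a replicate check. The deposited table held 1 FPKM value per gene and library, a fragment count scaled for transcript length and library size. Read counts were not used here. Low values within a chosen window gave depths of about 16800000 fragments in the control library and 17500000 in the SOX17 siRNA library. These depths are approximate and depend on the window. Unless stated otherwise, log2 ratios are log2((SOX17 siRNA + 1)/(control siRNA + 1)) of FPKM, which understates the differences of low genes, and folds printed beside a gene are plain ratios of its FPKM values. At the estimated depth, counting error alone gives this log2 ratio of a 2 kb transcript a 95% half-width of about 0.34 at 1 FPKM, 0.25 at 5 FPKM and 0.15 at 20 FPKM, and it leaves out all differences between cultures. A gene is called higher or lower where its log2 ratio reached 0.58 in size, which asks for more than 1.5-fold in plain ratio at low levels, and other genes are given as values.

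SOX17, the siRNA target, was lower in the library that received its siRNA. It stood at 14.7 FPKM in the control library and 6.85 FPKM in the SOX17 siRNA library, 46.6% of the control level, a 2.15-fold difference and a log2 ratio of -0.99996. The spread of log2 ratios among the 500 genes nearest in level was 0.21, and SOX17 ranked 48 from the lowest of the 11210 genes past the filter. The gene (identifier MSTRG.22357) lies on chromosome 8 from 54457935 to 54460892 of GRCh38, on the + strand, and its principal transcript has 2 exons in GENCODE release 29. The paralogs of the SOXF group were close to their control levels. SOX18 was at 8.41 FPKM in the control library and 7.94 FPKM in the SOX17 siRNA library, and SOX7, which shared a row with the overlapping gene PINX1, was at 44.9 and 41.6 FPKM.

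The series title names E2F1, a transcription factor that drives genes of S phase entry. E2F1 was at 4.74 FPKM in the control library and 6.32 FPKM in the SOX17 siRNA library, a 1.33-fold ratio and a log2 ratio of 0.35, below the size called higher. The spread among the 500 genes nearest in level was 0.25, and E2F1 lay at percentile 90 of these genes. Its locus (MSTRG.14879) spans chromosome 20 from 33675477 to 33686385 of GRCh38 on the - strand, with 7 exons in the principal transcript. Of the 18 measured genes of the E2F and RB family, 11 had a log2 ratio above 0 and 0 were called higher or lower. RBL1, a pocket protein of the RB family, had the highest ratio at 0.48 (3.74 to 5.61 FPKM from the control to the SOX17 siRNA library), followed by E2F8 at 0.47 (2.94 to 4.47 FPKM), while RBL2, another pocket protein, had the lowest at -0.34 (10.2 to 7.81 FPKM). The family's median log2 ratio was 0.09, at percentile 97.0 of 10000 random lists of the same size matched on level, and it lay above their central 95% without a filter on low values or with genes of at least 5 FPKM.

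The 2 libraries were close to each other for most genes. Pearson's r of log2(FPKM + 1) was 0.989 across the 11210 genes, which are not independent replicates, and 95.4% of the genes lay within 1.5-fold with the pseudocount. By the fixed rule of size, on the same scale, 41 genes were at least 2-fold higher in the SOX17 siRNA library and 47 were at least 2-fold lower. SOX17 itself lay just short of the 2-fold rule, which includes the pseudocount. In a simulation of 2 libraries at a single depth, averaged from both estimates, counting noise alone put 10 unchanged genes past the rule. Restricting the count to genes of at least 5 FPKM left 13 higher and 20 lower of 8591, and rescaling the libraries to equal sums without the 50 most abundant genes gave 53 higher and 40 lower. The counts were 140 and 142 with a pseudocount of 0.1, 79 and 86 with 0.5, 25 and 34 with a mean of at least 1 FPKM, and 63 and 100 with clone-named rows kept.

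Among genes of at least 5 FPKM, the 12 with the highest ratios had varied roles. GINS4, a subunit of the complex that opens DNA at replication forks, was 2.48-fold higher (6.86 to 17.0 FPKM). BGN, which encodes the matrix proteoglycan biglycan, was 2.21-fold higher (6.04 to 13.3 FPKM), and MALAT1, a nuclear long non-coding RNA, was 2.21-fold higher (12.02 to 26.5 FPKM) in a row it shared with overlapping transcripts. PCGF1, a Polycomb group protein, was 2.63-fold higher (4.69 to 12.3 FPKM) and FLVCR1, a membrane transporter, 3.46-fold higher (1.58 to 5.47 FPKM). The others included RGPD5, AUNIP, PLEKHA8P1, the DLEU2 and MIR15A row, SLC4A11 and LMLN. RGPD5 belongs to a family of near-identical copies and PLEKHA8P1 is a pseudogene, so their levels are uncertain. Of the higher genes named here, only BGN and LMLN had a p-value below 0.05 in the authors' deposited table. The ratios of the other named genes are therefore uncertain as well.

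The 12 genes with the lowest ratios included cytokines and a chemokine receptor. CCL20, a chemokine gene on chromosome 2 from 227805739 to 227817564, was 3.08-fold lower in the SOX17 siRNA library (78.3 to 25.4 FPKM). CSF3, which encodes the granulocyte growth factor G-CSF, was 2.86-fold lower (78.0 to 27.2 FPKM), IL1B 4.23-fold lower (5.72 to 1.35 FPKM) and ACKR3, a scavenging receptor for CXCL12, 2.66-fold lower (40.5 to 15.2 FPKM). KIF27, a kinesin, was 19.9-fold lower (8.15 to 0.410 FPKM), HDAC11, a histone deacetylase, 8.28-fold lower (15.0 to 1.81 FPKM), and EXOC6, a subunit of the exocyst, 2.63-fold lower (76.1 to 28.9 FPKM). The lowest ratio of all belonged to WFDC21P, annotated as a pseudogene on chromosome 17 from 60079309 to 60091885, at 71.8 FPKM in the control library and 0.359 FPKM in the SOX17 siRNA library. CNPY1, ZNF791, PTPRD and METAP1D made up the rest. WFDC21P, EXOC6, CNPY1 and ZNF791 had p-values above 0.05 in the authors' deposited table, so their ratios are uncertain. The other lower genes named here had p-values below 0.05 there.

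**Figure D1:**
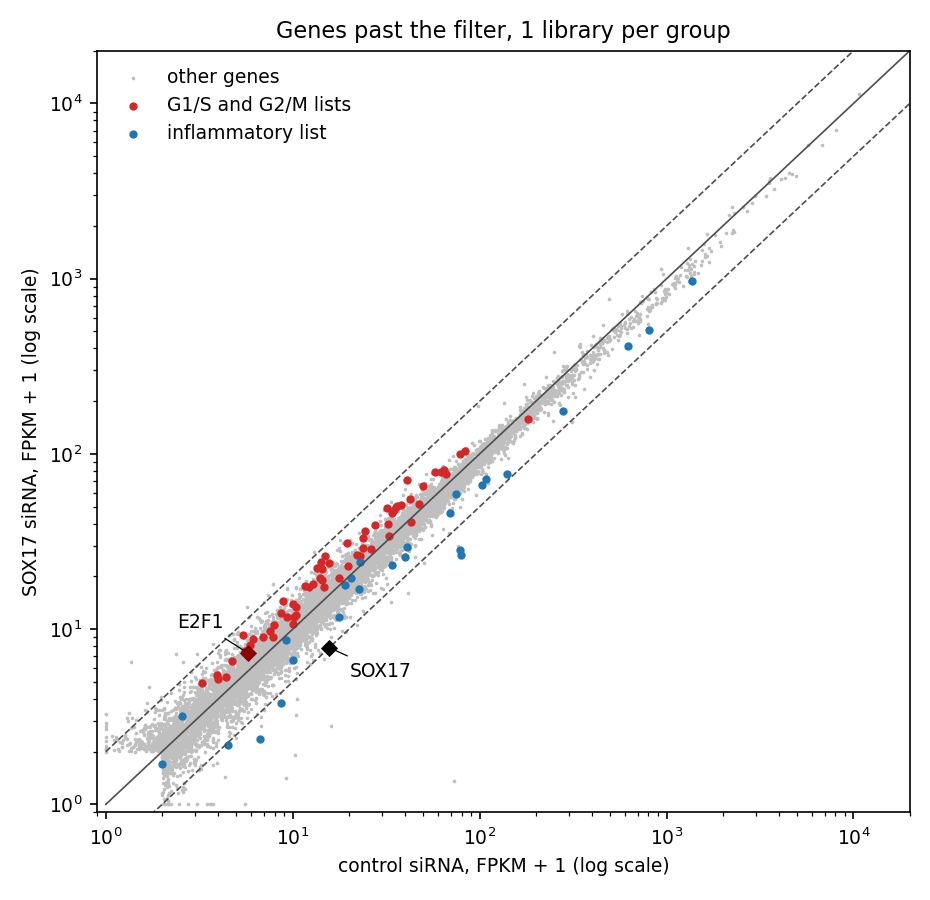
FPKM + 1 of the 11210 genes past the filter in the control siRNA library (x axis, log scale) against the SOX17 siRNA library (y axis, log scale), 1 library per group; the solid line marks equal values, the dashed lines 2-fold differences, and diamonds mark SOX17 and E2F1. The cell cycle lists (red) lie mostly above the line of equality and the inflammatory list (blue) mostly below it.

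Cell cycle genes were higher as groups in the SOX17 siRNA library. Of the 30 measured genes of the G2/M and mitosis list, 29 had a log2 ratio above 0, 9 were called higher and 0 lower. ANLN, a scaffold protein of the cleavage furrow, was at 40.0 FPKM in the control library and 70.1 FPKM in the SOX17 siRNA library (1.75-fold), KIF23, a motor of the central spindle, at 13.2 and 23.3 FPKM (1.77-fold), and BUB1, a spindle checkpoint kinase, at 12.5 and 21.4 FPKM (1.71-fold). The lowest members were NUSAP1, in a row with overlapping genes, at 41.8 and 40.0 FPKM, CENPA, also in a shared row, at 25.2 and 27.5 FPKM, and ECT2 at 22.0 and 25.1 FPKM. The proliferation marker MKI67 and the mitotic kinase CDK1, chosen after their values were seen, were at 7.85 and 13.4 FPKM and at 30.9 and 48.4 FPKM. The list's median log2 ratio was 0.49, and 0 of 10000 random lists matched on level had a median as high.

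The list of G1/S and E2F target genes, which holds the replication licensing and nucleotide synthesis genes, went the same way with smaller ratios. Of its 33 measured rows, 32 had a log2 ratio above 0, 3 were called higher and 0 lower. GINS2, of the same complex as GINS4, was at 4.43 FPKM in the control library and 8.21 FPKM in the SOX17 siRNA library (1.85-fold), and MCM10, a replication initiation factor, at 2.29 and 3.95 FPKM (1.73-fold). FEN1, in a row with overlapping genes, was at 180.3 and 157.9 FPKM, MCM5 at 31.9 and 33.1 FPKM, and E2F7 at 9.02 and 9.77 FPKM. The list's median was 0.35, and 0 of 10000 random lists reached it. Histone genes had a median of 0.20 over 7 measured rows, at percentile 99.1. The list gave 33 symbols, of which 13 were found in the table, and with means in place of medians or without the member of largest difference it lay inside the central 95% of random lists. H2AX was at 61.6 and 83.4 FPKM and H2AC6 at 4.80 and 6.09 FPKM.

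The p53 target and cell cycle inhibitor list showed no shift of this kind. Its 17 measured rows had a median of -0.03, at percentile 50.2, and 0 were called higher or lower. CDKN1A, the inhibitor p21, was at 322 FPKM in the control library and 247.2 FPKM in the SOX17 siRNA library, a log2 ratio of -0.38, and SESN1 at 10.2 and 12.9 FPKM. The apoptosis regulators had a median of -0.02 over 17 rows, at percentile 53.7, with BBC3, in a row with an overlapping microRNA gene, at 16.1 and 12.8 FPKM and BCL2L11 at 0.709 and 1.299 FPKM.

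Inflammatory adhesion and chemokine genes were lower as a group in the SOX17 siRNA library. Of 26 measured genes, 24 had a log2 ratio below 0, 14 were called lower and 0 higher. CCL20, IL1B and CSF3 had the lowest ratios. The endothelial adhesion molecules VCAM1 and ICAM1 and the chemokine CXCL8, which were chosen after their values were seen, were at 138.8 and 76.2 FPKM, 277.6 and 174.4 FPKM, and 807.2 and 508.7 FPKM in the control and SOX17 siRNA libraries. The highest members were IL33 at 1.57 and 2.21 FPKM, CXCL10 at 22.0 and 23.3 FPKM, and IRF1 at 19.6 and 18.7 FPKM. The median log2 ratio was -0.58, and 0 of 10000 random lists had a median as low.

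Interferon-stimulated genes did not share this direction. Their 27 measured rows had a median of 0.04, 19 rows lay above 0, and 1 was higher by the fixed size, IFIT2, an antiviral RNA-binding protein, at 2.91 and 4.97 FPKM in a row with overlapping genes. CMPK2 was at 3.15 and 5.10 FPKM, IFIT1 at 12.5 and 18.5 FPKM, and IFI27 at 1338 and 1137 FPKM. The median lay at percentile 97.7 and was inside the central 95% of random lists under 7 alternative settings and above it under 8, among them the mean of 0.12, at percentile 100, and the median of 0.10 after the length, GC and level trends, at percentile 99.2. Of 13 antigen presentation rows, NLRC5, an activator of MHC class I genes, was higher (4.97 to 9.41 FPKM), HLA-F was at 9.50 and 7.17 FPKM, and the median was -0.13, at percentile 11.99.

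**Figure D2:**
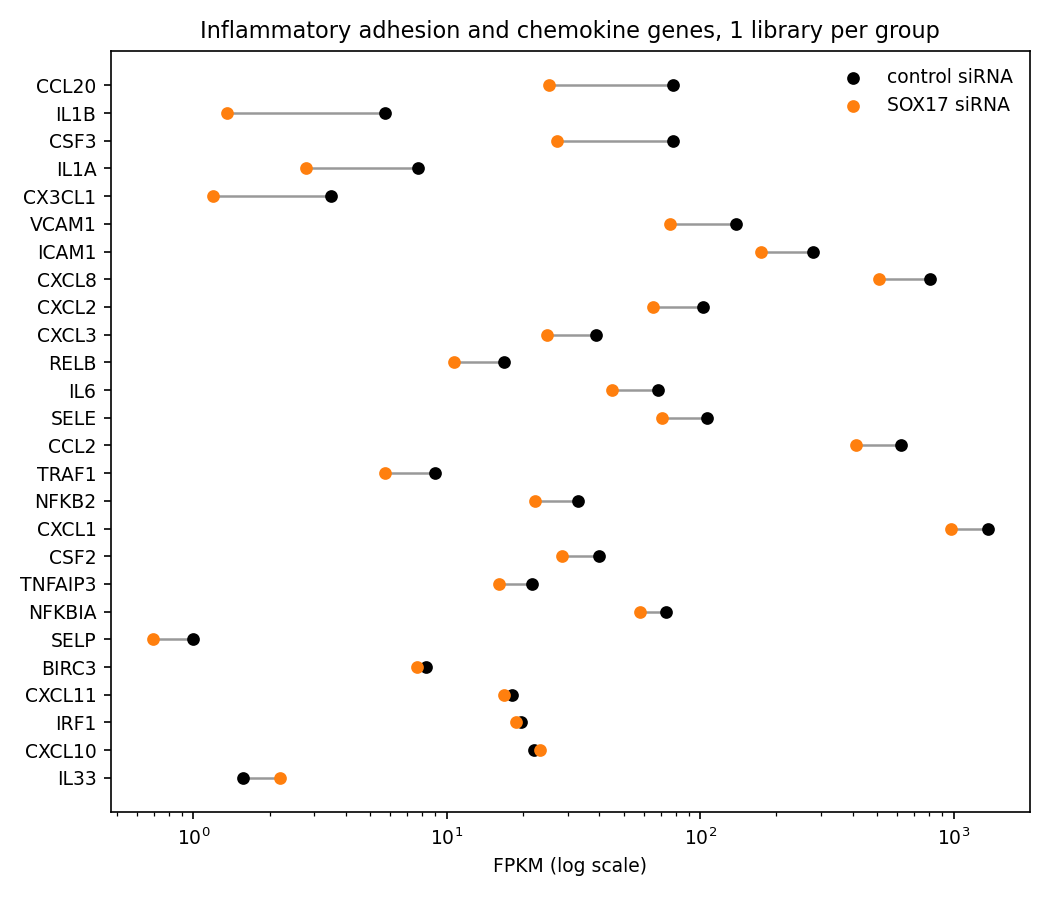
FPKM (x axis, log scale) of the 26 measured inflammatory adhesion and chemokine genes (y axis) in the control siRNA library (black) and the SOX17 siRNA library (orange), 1 library per group, ordered by log2 ratio; lines join the values of each gene. The SOX17 siRNA value is the lower of the pair in 24 of the 26 genes, with CXCL10 and IL33 at the bottom as the exceptions.

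Among 19 pan-endothelial rows, VWF, the von Willebrand factor gene, was lower (44.4 to 24.7 FPKM), and the remaining 18 were not called higher or lower. CLDN5, a tight junction protein, was at 100.2 and 76.3 FPKM, FLT1, a VEGF receptor, at 17.9 and 24.3 FPKM, and CLEC14A at 62.4 and 84.4 FPKM. The median was -0.08, at percentile 33.98. In the arterial and Notch list, 3 of 16 genes were lower and 0 were higher. The lower genes were CXCR4, the CXCL12 receptor, at 2.20 and 0.626 FPKM, SEMA3G at 1.19 and 0.271 FPKM, and LTBP4, a TGF-beta binding protein, at 4.27 and 2.11 FPKM, all at levels below 5 FPKM. The Notch ligand JAG1 was at 44.6 and 45.9 FPKM, and the arterial matrix gene FBLN5 at 5.87 and 8.01 FPKM. The arterial median was -0.08, at percentile 16.04, it was above 0 after the rescaling to equal sums, and the mean of -0.18, at percentile 2.43, lay below the central 95% of random lists. The 8 venous and lymphatic rows had a median of 0.15, at percentile 97.6, with 0 called higher or lower. LYVE1, a lymphatic hyaluronan receptor, was at 11.5 and 15.4 FPKM, RELN at 3.87 and 5.43 FPKM, and EPHB4 at 94.1 and 75.9 FPKM, and the percentile lay inside the central 95% under 7 alternative settings and above it under 8. The 6 lung capillary rows had a median of -0.14, at percentile 8.86, with RGCC at 17.1 and 11.9 FPKM.

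Genes tied to pulmonary arterial hypertension, the disease in which SOX17 variants have been described, were near their control levels as a group. Apart from SOX17, none of the 13 measured rows was called higher or lower, and the median was -0.02, at percentile 56.7. BMPR2, the BMP receptor most often mutated in the heritable disease, was at 15.6 FPKM in the control library and 19.9 FPKM in the SOX17 siRNA library, and ACVRL1 was at 52.2 and 48.4 FPKM. In the BMP and TGF-beta list, BMP4 was higher (8.93 to 14.8 FPKM), TGFB1 was at 102.2 and 79.98 FPKM, and the median of 22 rows was 0.02, at percentile 85.6. In the WNT list, LGR4, an R-spondin receptor, was higher (5.75 to 10.0 FPKM), TCF7L2 was at 6.07 and 8.24 FPKM, and MYC was at 27.3 and 23.6 FPKM. Its 15 rows had a median of 0.07, at percentile 96.1, and lay above the central 95% of random lists without a filter on low values (98.4), with the mean (98.7) and after the trends (a median of 0.12, at 98.4).

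Vascular function genes held members that went both ways. Among 22 vasoactive and antithrombotic genes, PLAT, the tissue plasminogen activator, was higher (248.4 to 381.4 FPKM), as was THBD, the thrombin receptor thrombomodulin (5.30 to 8.49 FPKM), and PTGS2, the inducible cyclooxygenase, was lower (29.4 to 15.96 FPKM), as was VWF. Their median was 0.03, at percentile 96.2. Of 14 shear-responsive genes, THBD was higher and HMOX1, which encodes heme oxygenase 1, was lower (324.6 to 209.7 FPKM). KLF2 was at 19.3 and 20.6 FPKM, and the median of the shear-responsive list was 0.02, at percentile 91.3. The 22 junction and barrier rows had a median of -0.09, at percentile 16.8, with 0 called higher or lower. CDH5, the gene of VE-cadherin, in a row with an overlapping gene, was at 153.7 and 124.6 FPKM, and ANGPT1 at 2.05 and 3.23 FPKM. Of 24 growth factor and angiogenesis rows, CXCR4 and PDGFB (18.3 to 10.7 FPKM) were lower, FGF16 was at 6.98 and 4.56 FPKM, and the median was 0.02, at percentile 83.6. Of 28 matrix rows, BGN was higher and MMP10, a matrix metalloproteinase, was lower (41.0 to 26.9 FPKM). HSPG2, the basement membrane proteoglycan perlecan, was at 409.9 and 301.5 FPKM, LOX at 56.2 and 79.8 FPKM, and the median was -0.05, at percentile 74.9. The 11 rows of the endothelial-to-mesenchymal list had a median of -0.05, at percentile 44.2. SNAI1 was at 5.41 and 4.04 FPKM and VIM at 2555 and 2559 FPKM.

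Ribosomal protein and respiratory chain genes lay below their control levels by small amounts. All 36 cytosolic ribosomal protein rows had a log2 ratio below 0, and none was called lower. RPL37 was at 711.0 FPKM in the control library and 475.4 FPKM in the SOX17 siRNA library, and RPL19 at 1366 and 1206 FPKM. The median was -0.30, and 0 of 10000 random lists were as low. All 24 nuclear-encoded oxidative phosphorylation rows were also below 0, with a median of -0.20, at percentile 0.24. COX7C, in a row with an overlapping gene, was at 313.9 and 222.7 FPKM, and UQCRC1 at 92.8 and 90.6 FPKM. The mitochondrially encoded genes differed from these, with a median of 0.03 over 10 rows, at percentile 99.8 among random lists whose own median was -0.13. MT-ND3 was at 4705 and 3937 FPKM and MT-ND6 at 2233 and 2578 FPKM. Their mean log2 ratio was -0.0025, so mean and median differed in sign, and with random lists not matched on level the percentile was 72.6. The log2 ratio also followed transcript length and GC content across genes. The tenth of genes with the shortest transcripts had a median of -0.13, and the tenth with the longest 0.08, while the tenth of lowest GC content had 0.06 and the tenth of highest -0.08. Ribosomal protein and respiratory chain transcripts are short, and after a fit of these trends and of level on the other genes their median residuals were -0.16 and -0.08.

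Of the metabolic and stress lists, the cholesterol and fatty acid synthesis genes had a median of -0.17 over 23 rows, at percentile 0.05, with 0 called higher or lower. INSIG1, a sterol sensor of the endoplasmic reticulum, was at 53.9 and 37.7 FPKM, SCD, the stearoyl-CoA desaturase, at 85.3 and 62.3 FPKM, and ACACA, acetyl-CoA carboxylase, at 19.8 and 22.9 FPKM. The unfolded protein and integrated stress response list had a median of -0.16 over 19 rows, at percentile 1.41, and lay inside the central 95% with genes of at least 5 FPKM or with means in place of medians. DDIT4, a stress-induced inhibitor of mTORC1, was at 24.2 and 16.8 FPKM, HSPA5, the chaperone BiP, at 423.9 and 368.9 FPKM, and DDIT3, in a row with an overlapping gene, at 10.6 and 12.99 FPKM. Of 26 hypoxia and glycolysis rows, ANKRD37 was lower (4.99 to 2.98 FPKM) and the median was -0.05, at percentile 69.5. Heat shock and immediate early genes had a median of -0.08 over 16 rows, at percentile 30.4, with ZFP36 at 4.79 and 3.18 FPKM. The 22 housekeeping rows had a median of -0.02, at percentile 94.5, with VCP at 238.9 and 210.0 FPKM. The 11 genes of the RNA interference machinery, measured because both groups received an siRNA, had a median of -0.04, at percentile 28.1, with DICER1 at 6.07 and 9.29 FPKM and AGO4 at 2.95 and 2.28 FPKM.

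**Figure D3:**
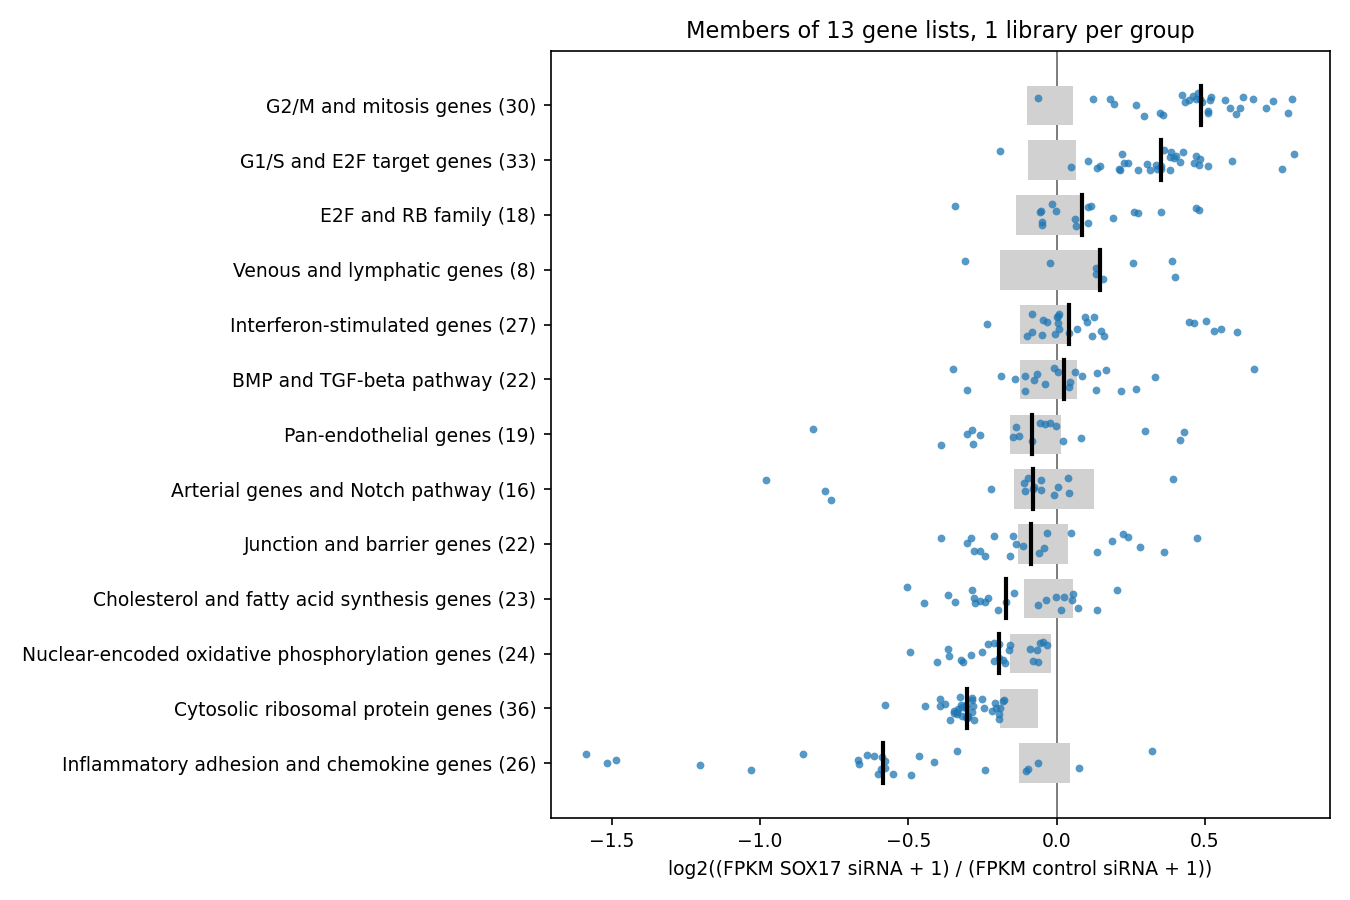
Log2 ratio of FPKM + 1, SOX17 siRNA over control siRNA (x axis), for the measured members (points) of 13 of the 37 gene lists (y axis, number of rows in parentheses), 1 library per group; black bars are list medians and grey boxes the central 95% of the medians of 10000 random lists matched on level. The G2/M and G1/S medians of 0.49 and 0.35 lie to the right of their boxes and the inflammatory median of -0.58 to the left.

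Of the 31 lists with at least 5 measured rows, 6 had a median above the central 95% of random lists and 5 below it. By chance 1.55 in all would be outside if members of a list varied independently, as members of the random lists do. Where members vary together, more lists lie outside without a difference between the conditions, and this was not measured. These percentiles describe the 2 libraries and are not tests of the conditions. The sign of the median turned under all 3 rescalings for the apoptosis, pulmonary arterial hypertension and housekeeping lists, and under the rescaling to equal sums for the arterial, endothelial-to-mesenchymal, matrix, heat shock, hypoxia, junction, pan-endothelial, RNA interference and p53 lists.

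Of the measured markers of leukocytes, smooth muscle cells, fibroblasts and lung epithelium, 0 reached a log2 ratio of 0.58 in size. This count covers 4 of the 5 fixed lists of other cell types, and the result of the remaining list is left out. Of 13 leukocyte markers, only CD68 passed the filter, in a row with overlapping genes, at 783.4 and 779.3 FPKM. Of the smooth muscle and pericyte markers, 4 of 14 passed, with RGS5 at 421.6 and 364.3 FPKM and ACTA2, in a row with overlapping genes, at 23.6 and 23.3 FPKM. Among fibroblast markers, PDGFRA, in a row with overlapping genes, was at 18.5 and 17.5 FPKM and FAP at 1.19 and 2.09 FPKM. Among lung epithelial markers, KRT18 was at 99.6 and 108.3 FPKM and KRT19 at 39.4 and 49.2 FPKM.

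The authors' deposited table also gave a p-value and a q-value per row, from a comparison of these 2 pooled libraries and not of the conditions. No row of the authors' deposited table had a q-value below 0.05. Of the 13170 rows with a p-value below 1 in the authors' deposited table, 290 had a p-value below 0.05. Of these 290 rows, 145 were higher and 145 lower in the SOX17 siRNA library. Their share of the 13170 rows is below 0.05 itself, so the count alone shows no excess of low p-values. The lowest q-value in the authors' deposited table was 0.0823, shared by 8 rows, 7 lower and 1 higher. The lower rows with a symbol were CCL20, CSF3, ACKR3, KIF27, ABCG1 (13.7 to 5.76 FPKM) and UBAC2-AS1. The higher row was IGFBP1, listed at 0 in the control library and at 0.849 FPKM in the SOX17 siRNA library, per the authors' deposited table. UBAC2-AS1 and IGFBP1 were below 1 FPKM in both libraries and did not pass the filter used here. ABCG1, UBAC2-AS1 and IGFBP1 were chosen after their values were seen. All 8 rows held the lowest p-value in the authors' deposited table. Their shared q-value is that p-value times the number of rows with a p-value below 1, divided by 8. It therefore does not rank these rows. In the authors' deposited table SOX17 had a p-value of 0.0003 and a q-value of 0.329, and E2F1 a p-value of 0.1905 and a q-value of 0.9996.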

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

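Assembled gene models without a gene name entered no comparison in the report, and 72 of the 196 such rows reached 5 FPKM in at least 1 library. Of these 72, 31 overlapped an annotated protein-coding gene, 11 were, with the pseudocount, at least 2-fold higher in the SOX17 siRNA library, 16 were at least 2-fold lower, and 7 were listed at 0 in 1 library. The row MSTRG.18503, listed on chromosome 5 from 6633427 to 6674386, was at 118.3 FPKM in the control library and listed at 0 in the SOX17 siRNA library. It has the same locus as SRD5A1, whose own row was at 3.38 and 3.44 FPKM. The row MSTRG.13532, on chromosome 2 from 73984144 to 73984354, was listed at 0 in the control library and at 91.2 FPKM in the SOX17 siRNA library. How fragments were divided between models at the same locus cannot be checked without reads, so the value of MSTRG.18503 is no measure of a gene there. These 2 examples were chosen after their values were seen, and no explanation was tested.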

How the results depend on the processing

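The alternatives with rows of a single symbol, rows with an authors' p below 1, clone-named rows and trend residuals were added after seeing the data. The directions of the G1/S, G2/M, inflammatory, ribosomal protein, oxidative phosphorylation and cholesterol list medians, and their place outside the central 95% of random lists, were the same under all 15 alternatives, of which 2 change only the random lists and so leave the medians as they are. The number of genes at least 2-fold higher and lower, 41 and 47, was 140 and 142 with a pseudocount of 0.1, 79 and 86 with 0.5, 13 and 20 at 5 FPKM or more, 25 and 34 with a mean of at least 1 FPKM, and 63 and 100 with clone-named rows kept. The 1.5-fold threshold gave 265 and 254 genes and the 3-fold threshold 3 and 13. Fewer or more genes enter by construction under these filters and thresholds, and low genes pass more easily with a small pseudocount. Rescaling to equal sums without the 50 most abundant genes multiplied the SOX17 siRNA values by 1.065 and moved the G1/S median to 0.44, the G2/M median to 0.58 and the inflammatory median to -0.50, a shift of all genes by construction. Removing the length, GC and level trends moved the inflammatory median to -0.52. Lists above the central 95% of random lists numbered 3, in place of 6, with unmatched random lists and also without each list's member of largest difference. The mean of the mitochondrially encoded list was -0.0025, the opposite sign of its median, and that of the arterial list was -0.18, at percentile 2.43. The cause of these differences was not tested. The log2 ratios of SOX17 and E2F1 moved by less than their spread under each of 5 alternatives, and of the 140 values of single genes 15 moved, all under smaller pseudocounts. Of 402 list medians under the 13 alternatives that recompute them, 350 moved by less than the spread of random lists. No paired analysis was possible because there is 1 library per group, and no replicate could be left out. Restricting to rows marked as tested was not run, since no such mark was used here. Depth limits genes near 1 FPKM, where counting error alone spans a log2 half-width of 0.34.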

Other observations

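The gene families in the first paragraphs, the tests of leukocytes, of interferon-stimulated genes and of scaling were chosen after the results were seen, and the tests of length, GC content and level were chosen before theirs. Percentiles of families chosen this way partly restate why they were picked and are not separate evidence. More families were scored than are given here, and some of them lay inside the central 95% of random lists. Of 16 condensin, cohesin and SMC genes, which shape chromosomes and which no fixed list holds, 13 had a log2 ratio above 0, with a median of 0.25, and NCAPG was at 16.1 and 23.0 FPKM in the control and SOX17 siRNA libraries. After removal of the length, GC and level trends their median was 0.23, at percentile 100 of random lists. Kinesins, the motors that include several spindle proteins, numbered 26, of which 3 belong to the G2/M list. The remaining 23 had 19 above 0, a median of 0.18 and, after removal of the trends, a median of 0.16 at percentile 99.8, with KIF20B at 4.85 and 8.34 FPKM. Of 10 Fanconi anaemia genes, which act in the repair of interstrand crosslinks, 9 lay above 0, with a median of 0.20 and FANCI at 11.8 and 17.2 FPKM, but after removal of the trends their median of 0.18 lay at percentile 96.3, inside the central 95% of random lists.

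Of 14 collagen rows 12 had a log2 ratio below 0, with a median of -0.16 that lay between -0.14 and -0.08 under the 3 rescalings and was -0.17 after removal of the trends. This rested in part on 5 rows that the matrix list already holds, among them COL4A1 (125.2 to 99.9 FPKM) and COL4A2 (107.9 to 90.4 FPKM), the basement membrane pair. The 9 other rows had a median of -0.13 and, after removal of the trends, -0.09 at percentile 14.2, inside the central 95% of random lists. Proteasome subunits had a median of -0.12, with 33 of 37 rows below 0, and after removal of the trends the median was -0.013. Mitochondrial ribosome genes had a median of -0.08 over 78 rows, 0.0031 under 1 rescaling, and -0.0088 after removal of the trends.

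Both cell cycle lists were higher in the SOX17 siRNA library. After trends with length, GC content and level were removed, the 63 rows had a median residual of 0.430 (spread of random lists 0.0273). Their median log2 ratio before removal was 0.415, so these values argue against the fitted trends as the cause of the shift. A scaling difference does not account for the shift either, since it would move genes of the same level alike. The lower of both list medians lay 0.37 above the median of its level-matched random lists (spread 0.0419). This is the comparison that gave the list percentiles, and not separate evidence. An effect of the SOX17 knockdown, a difference in growth state between the pools and an off-target effect of the siRNA all stay open, and were not tested, since there is 1 library per group.

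The inflammatory list was lower in the SOX17 siRNA library, and 14 of its genes were at least 10 FPKM lower. Leukocytes as the source are argued against by the 7 leukocyte markers checked, of which the highest was CD14 at 0.326 FPKM in the control library. The 7 do not include CD68, the only 1 of the 13 fixed leukocyte markers past the filter. CD68 shared a row with overlapping genes and had a log2 ratio of -0.0075. A weaker innate response to transfection that includes interferon-stimulated genes is argued against as well, since their median lay 0.63 above the inflammatory median (spread 0.0592). The median residual after the length, GC and level trends was -0.52 (spread 0.0405), so those trends are not the whole cause. An effect of the SOX17 knockdown and an off-target effect of the siRNA stay open. A difference between the pools in culture or in the response to electroporation stays open too. None of these was tested.

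Ribosomal protein genes and oxidative phosphorylation genes were lower by small amounts, and both lists hold short transcripts. After removal of the length, GC and level trends the ribosomal protein median residual was -0.16 (spread 0.0266), 54.1% of its size, so the trends may account for a large part but not for all of it. For oxidative phosphorylation the residual was -0.084 (spread 0.0310), 42.9% of its size, and the trends and a difference in these transcripts cannot be told apart, because the residual lies beyond the spread of random lists but has lost most of its size. The source of the trends was not tested, and any difference between the 2 libraries is confounded with the groups.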
